A study of Mus musculus with 12 samples.

How the data were processed

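Total RNA of cerebrum and heart was extracted with the RNeasy Plus Mini kit and labelled with biotin for Affymetrix whole-transcript arrays, per the labels' protocols. The deposited table gives 1 value per transcript cluster and array, rounded to 2 decimals, for 35556 transcript clusters on 12 arrays. The authors processed the arrays in Affymetrix Expression Console, per the submitters' processing notes. The version, background correction, summary method and genome build are not given in the sources used here. The deposited values were taken as log2 intensity, because they ran from 1.9 to 13.11 and the natural log of the maximum of a 16-bit scanner is 11.1. Array medians were nearly equal, at 4.89 to 5, and the values were used without further normalization. A summary per transcript cluster can hide differences between exons, and normalization to equal medians would hide a shift of all transcripts.

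The supplied table of probe annotation listed 23099 of the transcript clusters. Of these, 21218 had 1 gene symbol (18820 distinct symbols), 1881 had several, and 12457 transcript clusters had no entry. Gene identifiers matched the supplied gene table for 21185 of the 21218, and 0 symbols changed. Transcript clusters with several symbols or none were left out of the comparisons and were tested apart, both kinds together. One item of the rule for named genes is not reported here.

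Groups were taken from the labels: tissue and treatment, with 3 arrays each. Nothing was averaged beforehand, since no pair of arrays had nearly identical values. The labels call the arrays biological replicates, and whether cerebrum and heart of equal number came from 1 mouse is not stated in them. The number of arrays limits the precision.

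Comparisons were made with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all transcripts of a comparison and a threshold of 0.05. Transcripts with a mean at or above the 40th percentile over the arrays in the fit were tested. PS was compared with MCT in each tissue separately, heart with cerebrum in MCT mice, and the difference of the PS effect between tissues over all 12 arrays. Gene lists were tested with camera at a preset correlation of 0.01, 1 transcript per gene (the one with the highest mean), for lists with at least 3 tested members, and again with an estimated correlation and with fry. The 44 lists cover brain regions, cell types, metabolism, stress and signalling and hold 727 genes, of which 645 were measured. Lists overlap in some members, such as Per1.

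Named genes were, in each direction, the 15 with the largest log2 difference among those past the threshold. Where fewer than 12 passed, those were filled up to 12 with transcripts of an unadjusted p under 0.01 whose groups did not overlap, described as not past. Up to 4 members of each list with the lowest p were added, up to 5 genes in each direction by the lowest p for the difference between tissues, and up to 4 members per list by fold between the tissues. Names of gene models and small RNAs were left out of naming but counted. The rule for named genes, the lists, the tests of the comparisons and the alternatives were fixed before the data were examined. Chosen after the data were seen were the alternatives described so, the tests of explanations, the list tests of the difference between tissues and the set of small RNAs. Ttr, Myl7, Dusp4, H2-Eb1, Tbr1, Bhlhe40, Flt1, Cnn1, Snora44, Pomc, Rnu2-10, Rnu12, Rny1 and, in cerebrum, Fkbp5 were chosen after their values were seen.

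The fits were tested on simulated data with the real means and spreads and a set of transcripts changed by known amounts, over 12731 transcripts in each case. Changes of 0.5, 1 and 2 on the log2 scale were recovered for 14.3%, 81.2% and 96.6% in cerebrum, 18.5%, 82.0% and 98.4% in heart, 11.9%, 54.7% and 96.8% for the difference between tissues, and 12.5%, 81.0% and 100% between heart and cerebrum. False calls were 3.2%, 5.34%, 1.905% and 4.76% of calls. The spread of each transcript was pooled over the groups of both tissues, and its noise was drawn independently of other transcripts. These rates therefore do not cover variation that transcripts of an array share. Alternatives covered other scalings, filters and transcripts tested, limma's intensity trend, a plain t statistic, array weights, blocks by replicate number or by treatment and number, other thresholds, and leaving out each array in turn.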

Results

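Gene expression was profiled in cerebrum and heart of mice of a humanized knock-in model of familial dysautonomia, an inherited disease of sensory and autonomic neurons. The mice received phosphatidylserine (PS), a membrane phospholipid, or its vehicle, medium-chain triglycerides (MCT), by gavage every other day for 3 months from 4 months of age. The PS dose was 200 mg/kg in a volume of 100 µl. The series asks whether PS affects gene expression in these mice. There were 12 arrays, 3 for each combination of tissue and treatment, and their small number limits the precision of every comparison. The labels conflict in places. The series design describes 6 FD mice (FD, familial dysautonomia), whereas the growth protocol speaks of 3 FD and 3 wild-type mice. Every array has the same genotype label, FDloxP/+. The dose is given per kg in the protocols and per day in the source names. Array medians lay between 4.89 and 5 on the log2 scale. Correlations across transcripts, which are not independent replicates, were 0.979 to 0.995 between arrays of a group, 0.973 to 0.992 between treatments within a tissue and 0.825 to 0.852 between tissues.

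The treatment groups differed in the expression of sex-linked transcripts. Xist, the long noncoding RNA expressed from the inactive X chromosome of females, was 8.92 to 9.86 in 5 arrays and 3.32 to 4.03 in the other 7. The Y-linked genes Eif2s3y, Uty and Kdm5d were low in those 5 arrays, at 3.41 to 3.78, 3.12 to 3.29 and 3.55 to 4.19, and high in the 7, at 7.25 to 8.67, 7.19 to 7.83 and 5.79 to 6.15. All 3 heart PS arrays and cerebrum PS 1 and PS 3 had the female pattern. Cerebrum PS 2 and all 6 MCT arrays had the male pattern. Sex pattern and treatment therefore coincided completely in heart and in all arrays but PS 2 in cerebrum. Arrays of equal number in the 2 tissues had different patterns for PS 2. The female pattern was in 3 of the 6 heart arrays and 2 of the 6 cerebrum arrays, a difference that an exchange of arrays within a tissue cannot give. Either not all mice gave both tissues or a sample was exchanged with one from outside the series, and the values do not settle which.

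**Figure D1:**
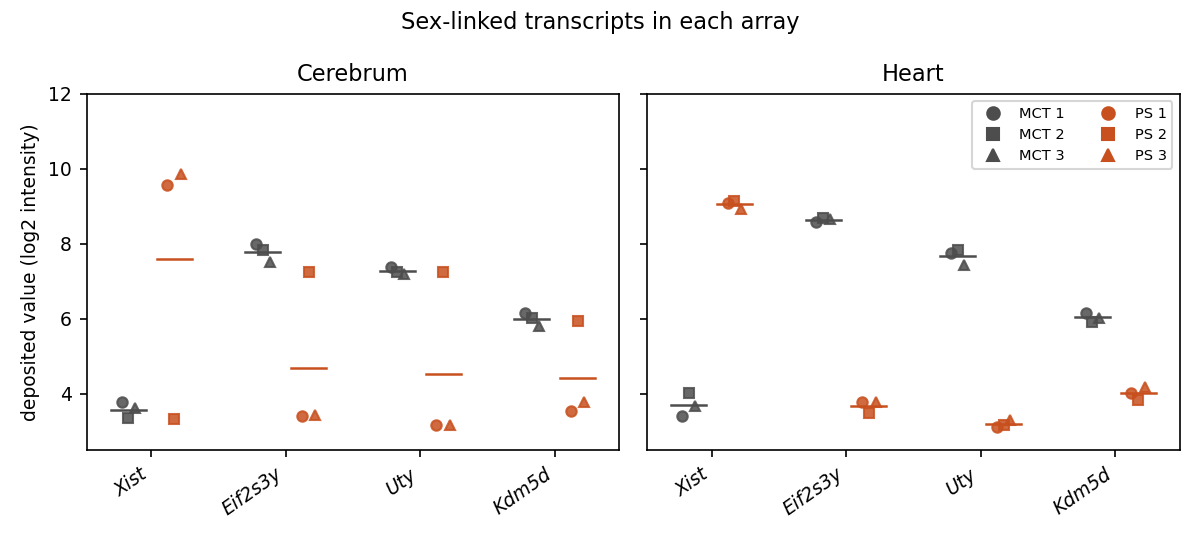
Deposited log2 intensity (vertical axis) of 4 sex-linked transcripts (horizontal axis) in cerebrum and heart, 1 point per array, with a line at each group's mean of 3 arrays. Xist was 8.92 to 9.86 in 5 PS arrays and at most 4.03 in cerebrum PS 2 and the 6 MCT arrays.

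Heart and cerebrum of the MCT mice had the expression of their tissues. Contractile genes were far higher in heart: the ventricular myosin light chain Myl2 was 12.02 ± 0.04 in heart and 3.93 ± 0.19 in cerebrum (SD, n = 3), and the calcium pump regulator Pln differed by 7.43 on the log2 scale. The fatty acid transporter Cd36 was 8.24 higher in heart. The synaptic vesicle fusion protein Snap25 was 12.34 ± 0.05 in cerebrum and 4.11 ± 0.18 in heart, and the astrocytic glutamate transporter Slc1a2 had a difference of −6.34. The lower mean of Myl2, Cd36 and Snap25 lay below the filter of 5.23, so the sizes of such differences are approximate. In limma, 9610 of 12734 transcripts passed an adjusted p of 0.05, 4480 higher in heart and 5130 higher in cerebrum. All 17 tested genes of cardiac contraction and calcium handling, all 38 of oxidative phosphorylation and all 21 of fatty acid oxidation were higher in heart. All 16 neuronal, 16 myelin, 12 striatal and 18 cholesterol synthesis genes tested were higher in cerebrum, the last with Sqle, an epoxidase of sterol synthesis, at −4.03.

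For PS against MCT in cerebrum, the comparison that the series asks about in brain, the named genes with the largest differences were lower in PS mice, and all 12 tested genes of the list for the striatum, a subcortical region, were lower. Tac1, the precursor of substance P, fell from 9.97 ± 0.23 to 6.96 ± 1.57 (SD, n = 3 per group), a difference of −3.01 ± 0.67 (SE, adjusted p = 0.0469). The retinoic acid receptor Rarb fell by 1.88, the dopamine receptor Drd3 changed by −1.897, and the neuronal peptidase Ecel1 fell from 7.95 ± 0.31 to 5.44 ± 0.32 (adjusted p = 0.0136). The choline transporter Slc5a7 fell by 1.68 and the vesicular acetylcholine transporter Slc18a3 by 1.03. The PS means of Drd3 (4.54) and Slc5a7 (4.74) lay below the filter of 5.04, so the size of their fall is uncertain. Genes that rose included the cell cycle inhibitor Cdkn1a, by 1.31 ± 0.20 (SE), the zinc finger transcription factor Zbtb16 by 1.16 ± 0.11 and the small heat shock protein Hspb1 by 1.28 and 1.25 for its 2 transcripts.

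For PS against MCT in cerebrum, 734 of 12733 transcripts passed an adjusted p of 0.05 in limma, 233 higher and 501 lower with PS. They belonged to 678 gene symbols, 224 higher and 454 lower, and 9 of them were transcripts of Hnrnpa3. The higher share of transcripts was 31.7%, against 41.9% after quantile normalization of the 12 arrays and 17.6% after centring arrays on their medians. Other named genes that rose were the lipoxygenase Alox12b (1.55), the glycosyltransferase Galnt9 (1.25), the mitochondrial ribosomal protein gene Mrps21 (1.25), Serpinb8 (1.23), the glycoprotein gene Lrg1 (1.21), Tuba8 (1.18), Rtn4rl2 (1.07), the prostaglandin synthase Ptgs2 (1.03) and the neuropeptide gene Npy (1.02). Further genes that fell were Sh3rf2 (−2.58), the vesicular transporter Slc10a4 (−2.15), the imprinted genes Dlk1 (−2.08) and Peg10 (−1.67), Zcchc12 (−1.82), Gpx3 (−1.74), Slc35d3 (−1.62) and the synaptic priming gene Unc13c, whose 3 transcripts differed by −1.80, −1.69 and −1.66. The PS means of Sh3rf2, Slc10a4 and Slc35d3 and the MCT means of Alox12b and Lrg1 lay below the filter of 5.04. The sizes of these differences are therefore uncertain. The groups did not overlap for 32.8% of transcripts, where chance gives 10%, and 3692 had an unadjusted p under 0.05. The count rested on single arrays: without MCT 1 or without PS 1 limma called 0 (2303 and 2945 at an unadjusted p under 0.05), without MCT 2 it called Ecel1 (−2.33) and the small nucleolar RNA Snora44 (−2.07) only, without PS 2 145 and without PS 3 1557. With the mean of the Striatum list as a covariate, chosen after the data were seen, 1 transcript passed, the hormone precursor Pomc (4.74), and 0 of the 734 passed. Tac1 and Rarb are members of that list, so their values in this fit are set in part by the covariate itself. Of genes outside the list, Sh3rf2 was at −0.32 ± 0.20 (SE) in this fit, and Ecel1 at −1.899 ± 0.27 and Cdkn1a at 1.93 ± 0.27 had wider errors than without the covariate. Over all alternatives together, the smallest differences in size were −0.15 for Slc35d3, −0.62 for Zcchc12, −0.73 for Slc10a4, 0.70 for Alox12b and 0.75 for Egr3. For Peg10 and Zbtb16 the smallest were −1.27 and 0.98.

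The Striatum list, genes enriched in the medium spiny neurons of the basal ganglia, had all 12 tested members lower in PS cerebrum, with 1 more below the filter and 2 not measured, with a median of −1.87 (camera adjusted p = 1.16e-06, and adjusted p = 0.619 with an estimated correlation). Of these, 4 fell over all transcripts tested, Scn4b (−1.17), Syndig1l (−1.53), Rarb and Tac1, and 12 adjusted over the list alone. Per array, the list's median relative to the MCT mean was −2.56 in PS 1, −2.29 in PS 2 and −0.71 in PS 3. Genes of myelin and oligodendrocytes were lower in 17 of 17, with a median of −0.49 (adjusted p = 1.50e-04, and adjusted p = 0.619 with an estimated correlation). Of these 4 fell, the oligodendrocyte membrane gene Opalin (−1.35), Qdpr (−0.68), the aspartoacylase Aspa (−1.18) and the myelin glycoprotein Mog (−0.73), and 9 adjusted over the list alone. The Cerebral cortex list had a median of 0.49 (adjusted p = 0.0139, and adjusted p = 0.619 with an estimated correlation), or 0.32 without MCT 2. Its one call over all transcripts was Fezf2, a transcription factor of deep-layer projection neurons (0.74), and adjusted over the list alone 3 rose, with Lamp5 (0.93) and Tbr1 (0.60) beside it, and Tle4 fell (−0.25). The Hypothalamus list (median −1.05, adjusted p = 0.157) and the Thalamus list (median −0.40, adjusted p = 0.248) did not pass. With the Striatum mean as a covariate the Myelin list had a median of −0.22 (adjusted p = 0.550) and the Cerebral cortex list one of −0.17 (adjusted p = 0.607).

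**Figure D2:**
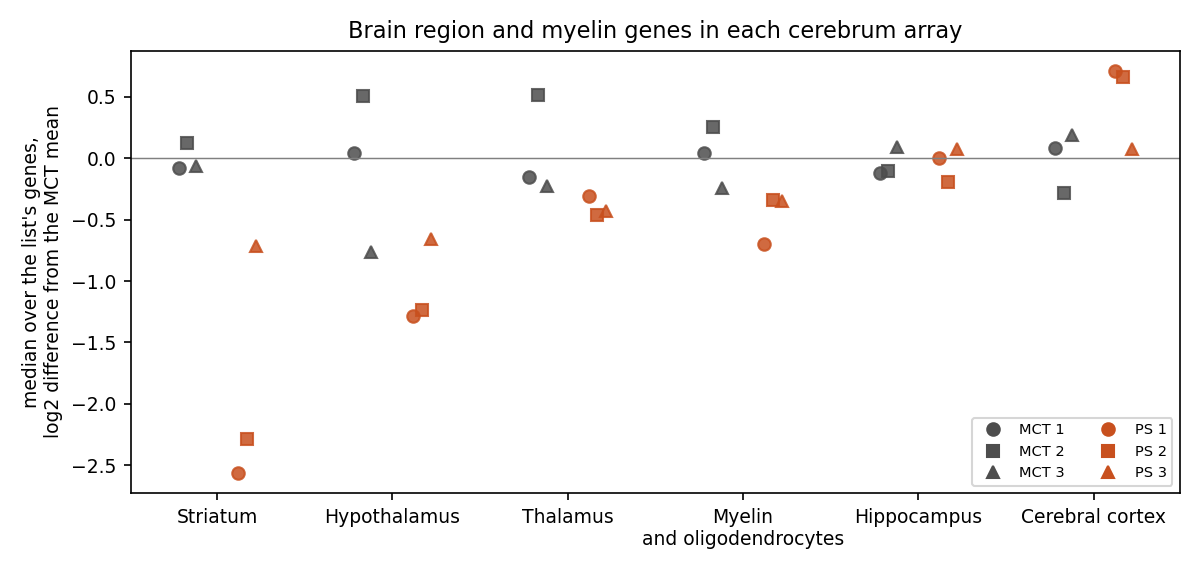
Median log2 difference from the MCT mean (vertical axis) over the genes of 6 lists of brain regions and myelin (horizontal axis), 1 point per cerebrum array. Striatal genes lay at −2.56, −2.29 and −0.71 in PS 1, PS 2 and PS 3.

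Genes induced by glucocorticoids were higher in PS cerebrum in 12 of 12 tested members, with 1 more below the filter, with a median of 0.43 (camera adjusted p = 1.06e-06, and adjusted p = 0.561 with an estimated correlation). Of these, 4 rose, Zbtb16, Cdkn1a, the clock gene Per1 (0.55) and the kinase Sgk1 (0.47), and 10 adjusted over the list alone. Fkbp5 was 7.38 and 7.51 in PS 1 and PS 3 and 6.37 in PS 2, against 6.55 to 6.83 in the MCT arrays. Targets of MAPK/ERK signalling that feed back on the pathway were higher in 14 of 14, with a median of 0.40 (adjusted p = 1.16e-06, and adjusted p = 0.619 with an estimated correlation). Of these, 5 rose, the ETS factor Etv5 (1.03), the phosphatases Dusp5 (0.88) and Dusp4 (0.93), Ier3 (0.57) and Spred2 (0.48), and 8 adjusted over the list alone. Immediate early genes, which neuronal activity induces, had a median of 0.54 with 20 of 21 higher (adjusted p = 3.00e-06, and adjusted p = 0.619 with an estimated correlation). The transcription factors Egr3 (1.22) and Nr4a2 (0.73) rose, and 10 members passed adjusted over the list alone, with Arc at 1.18 and Nr4a1 at 0.95. The list's median was 0.36 without PS 2. With the Striatum mean as a covariate these 3 lists passed, with medians of 0.73, 0.25 and 0.24. The sex pattern moved with treatment beside each of these lists in all arrays but PS 2.

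Ribosomal protein transcripts were lower in PS cerebrum in 24 of 25, with a median of −0.25 (adjusted p = 1.58e-05, and adjusted p = 0.619 with an estimated correlation). Of these, 3 fell, Rpl3 (−0.67), Rpl5 (−0.58) and Rps19 (−0.50), and 11 adjusted over the list alone. Oxidative phosphorylation genes had a median of −0.15 (adjusted p = 0.00381) with 3 that fell, Cycs, Ndufs4 and Uqcrb, and 7 adjusted over the list alone. Clock genes had a median of 0.20 (adjusted p = 0.0062) with Per2 (0.77) and Per1 past the threshold, 3 adjusted over the list alone with Bhlhe40 (0.67), and a median of 0.115 without PS 1. Antigen presentation genes had a median of 0.39 (adjusted p = 0.00366), with H2-Aa (0.67) past the threshold, 2 adjusted over the list alone with H2-Eb1 (0.43), and a median of 0.18 without PS 2. Endoplasmic reticulum stress genes (median 0.18, adjusted p = 0.00372, and 0.09 with adjusted p = 0.0595 without PS 2), endothelial genes (0.25, adjusted p = 0.0337) and 4 cardiac stress genes (0.33, adjusted p = 0.035) passed as lists without any member past the threshold, also adjusted over the list alone. The endothelial call ended without MCT 1 (adjusted p = 0.0524), MCT 2 (median 0.15, adjusted p = 0.102) or PS 2 (0.14, adjusted p = 0.268), and its median was 0.378 without MCT 3 and 0.435 without PS 3. With the Striatum mean as a covariate none of these 7 lists passed, and the medians of the clock genes and the endothelial genes were −0.05 and −0.17. For these 7 lists adjusted p = 0.619 with an estimated correlation. The other 26 of 39 lists did not pass, including phosphatidylserine and phospholipid synthesis (median −0.08, camera adjusted p = 0.248), in which the synthase Ptdss2 (−0.35) and Chpt1 (−0.43) fell, 2 also adjusted over the list alone. With fry, which does not compare a list with other genes, this list passed as lower (adjusted p = 0.0415). Nor did the Elongator list (adjusted p = 0.349), in which Elp4 (−0.45) and Urm1 (−0.40) fell, 2 also adjusted over the list alone. Median and test differed in sign for 4 lists and median and mean for 3.

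For PS against MCT in heart, the transcripts that separated PS from MCT mice most strongly were sex-linked: Xist was 9.05 ± 0.11 against 3.70 ± 0.32 (SD, n = 3 per group), and Eif2s3y, Uty and Kdm5d fell by 4.95, 4.48 and 2.02. The MCT mean of Xist and the PS means of the Y-linked genes lay below the filter of 4.935, so these sizes are approximate. Among the other named genes the largest difference was in Fkbp5, a co-chaperone of the glucocorticoid receptor and a sensitive target of it, which rose from 5.81 ± 0.09 to 8.28 ± 0.32 (adjusted p = 0.00137). Fam107a (1.82), the steroid sulfate transporter Slc10a6 (1.79) and the growth factor binding protein Igfbp3 (1.55) rose as well. Hsd11b1, the enzyme that regenerates active glucocorticoid, fell by 0.98 ± 0.12 (SE). Every PS heart had the female and every MCT heart the male pattern, so treatment and sex pattern could not be separated in heart.

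For PS against MCT in heart, 42 of 12736 transcripts passed in limma, 20 higher and 22 lower with PS. They belonged to 30 gene symbols, 18 higher and 12 lower, because the small nuclear RNA Rnu2-10, which was lower, and the X-linked Ddx3x, which was higher, had several transcripts each. Small RNAs made up 13 of the 42 transcripts, 12 of them from Rnu2-10 and Rnu12 and 1 from Rny1. Other named genes that rose were Spock2 (1.56), Baiap2 (1.49), the interferon-inducible Ifi207 (1.47), the kinase Map3k6 (1.45), Fam117b (1.14), the circadian gene Noct (1.13), Jade2 (1.12), Klf13 (1.05), the growth factor receptor Fgfr3 (0.98) and the X-linked helicase Ddx3x (0.95). B3galt2 (−1.40), Tmem256 (−1.18), Tmem14c (−0.93) and the integrin subunit Itgb6 (−0.86) fell. Wfdc17 (−1.40), Rpa3 (−1.29), Asb5 (−1.27) and Smim26 (−1.21) did not pass, although their groups did not overlap. Non-overlap held for 28.4% of transcripts, where chance gives 10%, and 3015 had an unadjusted p under 0.05. Without small RNAs and sex-linked genes 12 passed. The count was 11 without MCT 1, 4 without MCT 2 (Xist, Eif2s3y, Uty and Fkbp5), 3416 without MCT 3, 7 without PS 1, 12 without PS 2 and 6 without PS 3. Fkbp5, Xist, Eif2s3y and Uty passed in each of these 6 fits, Kdm5d in those where it was tested, and every other named heart gene missed the threshold in at least 2. With MCT 3 and PS 3 left out together, chosen after the data were seen because the atrial gene Myl7 was high there (8.53 and 6.80), 1176 passed.

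Glucocorticoid response genes were higher in PS heart in 13 of 13, with a median of 0.84 (camera adjusted p = 2.46e-09, and adjusted p = 0.625 with an estimated correlation). Of these, Fkbp5 and the anti-inflammatory leucine zipper gene Tsc22d3 (0.84) rose over all transcripts, and 13 adjusted over the list alone, with Zbtb16 at 1.88 and the metallothionein Mt2 at 1.29. Ribosomal protein transcripts were lower in 24 of 25, with a median of −0.41 (adjusted p = 4.65e-09, and adjusted p = 0.878 with an estimated correlation), or −0.27 without MCT 1. None passed over all transcripts and 7 fell adjusted over the list alone. Small nuclear and nucleolar RNAs, which were not a fixed list, had a median of −0.56 over 38 genes in heart and −0.39 over 36 in cerebrum. Of these genes, 2 passed as lower in heart, and 9 as lower and 1 as higher in cerebrum. Not every heart MCT array lay above the PS arrays: Snora44 was 6.58 in MCT 3 and 6.67 to 7.07 with PS.

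**Figure D3:**
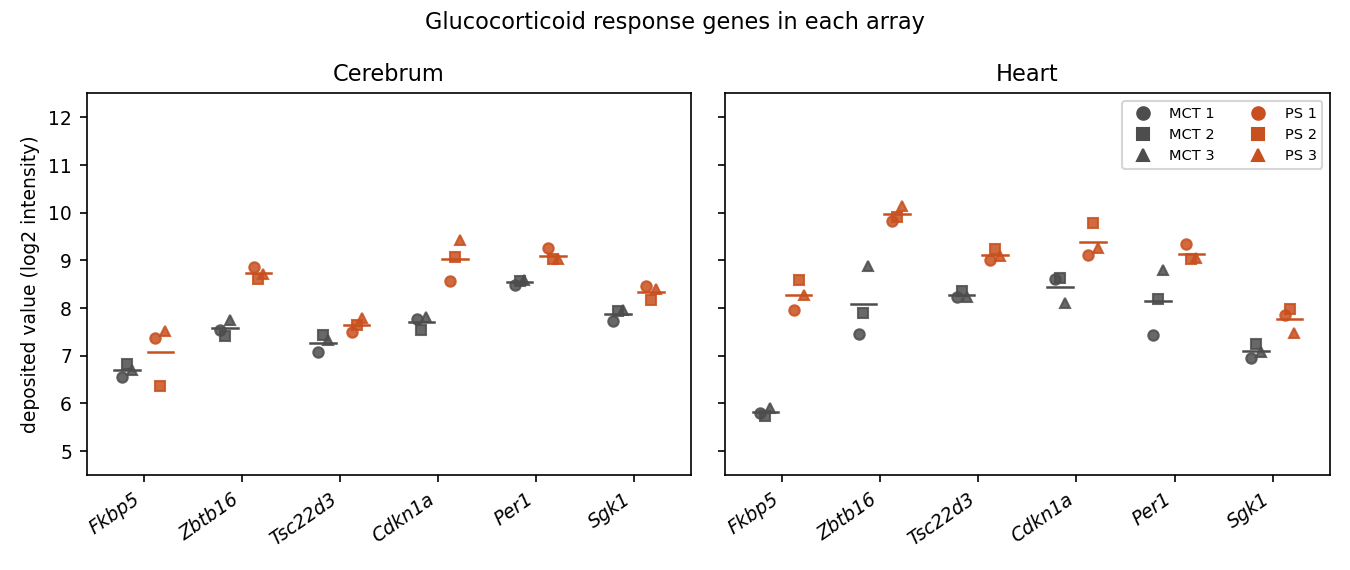
Deposited log2 intensity (vertical axis) of 6 glucocorticoid response genes (horizontal axis) in cerebrum and heart, 1 point per array, with a line at each group's mean of 3 arrays. Heart Fkbp5 was 5.81 ± 0.09 with MCT and 8.28 ± 0.32 with PS (SD).

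Endothelial genes had a median of 0.54 in heart (adjusted p = 0.0026), with the junction genes Pecam1 (0.58), Esam (0.63), Cdh5 (0.62), the clotting factor carrier Vwf (0.92) and the receptor Flt1 (0.71) making 5 past the threshold adjusted over the list alone. Smooth muscle and pericyte genes had a median of 0.49 (adjusted p = 0.0306, and 0.0546 without MCT 3), with Notch3 (1.01), Pdgfrb (0.67), Myh11 (0.98), Acta2 (0.66) and Cnn1 (1.22) making 5 adjusted over the list alone. The fibroblast and extracellular matrix list did not pass (median 0.645, 14 of 14 higher, adjusted p = 0.0742), and its median per array was 2.07 in PS 2 against 0.12 in PS 1 and 0.155 in PS 3. PS 2 was also highest for the endothelial list, at 0.65 against 0.487 and 0.51, and for the smooth muscle list, at 0.73 against 0.31 and 0.365. Endoplasmic reticulum stress genes had a median of 0.39 (adjusted p = 0.00175), with Chac1 (0.70), Pdia6 (0.60) and Herpud1 (0.86) past the threshold adjusted over the list alone. Oxidative phosphorylation genes had a median of −0.17 (adjusted p = 4.14e-04), with 1 past the threshold adjusted over the list alone, Ndufb3 (−0.67). No member of these 4 lists passed over all transcripts, and for each adjusted p = 0.878 with an estimated correlation. The list of 4 sex-linked transcripts passed too (adjusted p = 4.22e-04, adjusted p = 0.625 with an estimated correlation), with 1 that rose and 3 that fell, also adjusted over the list alone, and it did not pass without MCT 3 (adjusted p = 0.1502). The remaining 33 of 40 lists did not pass, among them fatty acid oxidation (median 0.02, adjusted p = 0.696), phosphatidylserine and phospholipid synthesis (0.06, adjusted p = 0.952, with Chka at 0.86 and Ano6 at 0.69 making 2 adjusted over the list alone) and Elongator (−0.08, adjusted p = 0.664). Median and test differed in sign for 8 lists, fatty acid oxidation and phospholipid synthesis among them, and median and mean for 6.

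**Figure D4:**
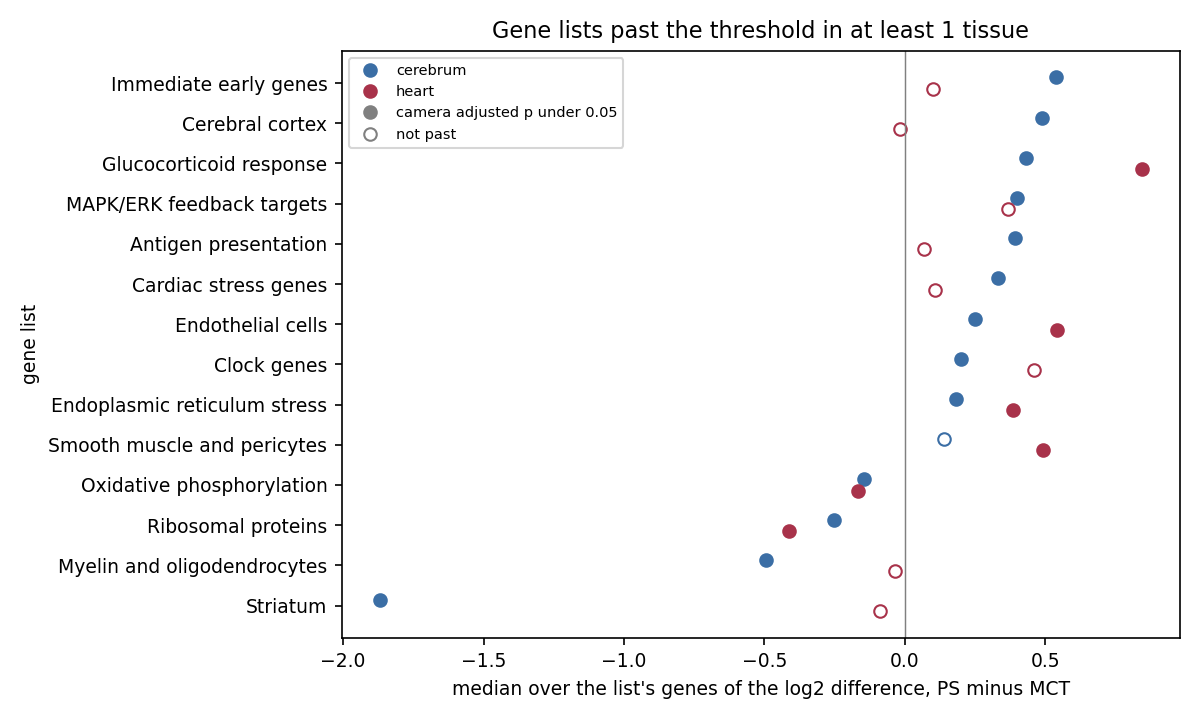
Median log2 difference of PS minus MCT (horizontal axis) for each gene list past the threshold in cerebrum or heart (vertical axis), sex-linked transcripts left out, with filled circles for a camera adjusted p under 0.05. Glucocorticoid response genes were at 0.43 in cerebrum and 0.84 in heart, and striatal genes at −1.87 in cerebrum.

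The difference between PS and MCT arrays was not the same in both tissues for some of these genes. Sex pattern coincided with treatment in heart and, but for PS 2, in cerebrum. The term PS effect therefore stands here for PS minus MCT, which is not separated from sex pattern. Peg10 was lower with PS in cerebrum (−1.67) and had a difference of 0.61 in heart, and Mamdc2 had a difference of −0.35 in cerebrum and 0.82 in heart. B3galt2 was lower in heart (−1.40) and differed by 0.06 in cerebrum, whereas Npy and Mrps21 were higher in cerebrum (1.02 and 1.25) and had differences of −0.16 and −0.23 in heart. In limma, 194 of 12731 transcripts passed the test of the difference of the PS effect between heart and cerebrum, coded heart minus cerebrum, 140 positive and 54 negative, a positive share of 72.2% against 85.4% after median centring. The 194 transcripts belonged to 179 gene symbols, and 9 of them were transcripts of Hnrnpa3. Of the named genes, Ecel1 was below the filter in heart and Nexn and Itgb6 below it in cerebrum. Mamdc2 did not pass in cerebrum (limma adjusted p = 0.0879), and its PS mean there, 4.96, lay below the cerebrum filter of 5.04. The Nexn difference came mostly from cerebrum, where it was 5.59 with MCT and 3.92 with PS. Among transcripts above the filter in both tissues, a restriction chosen after the data were seen, 165 of 11311 passed, 162 of them among the 194. The count was 3 without cerebrum MCT 1 (Ecel1, Mamdc2 and Mrps21), 38 without cerebrum PS 1, 39 without cerebrum MCT 2, 54 without cerebrum PS 2, 118 without cerebrum MCT 3, 364 without cerebrum PS 3, 76 without heart MCT 1, 89 without heart MCT 2, 58 without heart PS 2, 68 without heart PS 3 and 1629 without heart MCT 3. Of 9953 genes tested in both tissues, 0 passed in both in the same direction in limma, against 0.271 higher and 0.381 lower expected of independent lists. At an unadjusted p under 0.05, 316 were higher in both against 166.8 expected and 348 lower in both against 157.2.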

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

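All tests of explanations here, and the list tests of the difference between tissues, were chosen after the results were seen, except the counts over other groupings of the arrays, which were planned.

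The PS effect, that is PS minus MCT, differed between heart and cerebrum for 194 transcripts by the test of the difference itself. This test does not separate PS from sex pattern. Of 100 groupings of the treatments within tissues, drawn from all possible ones, 2 gave at least as many, the real one included. The highest other count was 311. These groupings also break up any treatment difference that the tissues share, so they cannot decide whether the effects differ. The groupings exchanged arrays in each tissue separately, whereas the series design gives 6 mice for the 12 arrays. With equal treatment and number as a block 22 passed, 20 of them among the 194. The grouping with 311 kept the real groups in heart and exchanged arrays in cerebrum, and its cerebrum part alone gave 0. Differences, heart minus cerebrum, were 2.62 for Ecel1, 1.17 for Mamdc2, 2.27 for Peg10, 2.14 for the actin-binding gene Nexn and 1.42 for Baiap2, and −1.48 for Mrps21, −1.46 for B3galt2, −1.02 for Itgb6, −1.18 for Npy and −1.10 for Pcsk1n, a regulator of prohormone processing. Ecel1 was below the filter in heart, and Nexn and Itgb6 were below it in cerebrum. The PS mean of Mamdc2 in cerebrum, 4.96, lay below the filter of 5.04 there. By list, the difference had a median of 1.67 for Striatum, −0.34 for Immediate early genes, 0.29 for Fatty acid synthesis and −0.50 for Cerebral cortex, each past the threshold with camera. With an estimated correlation adjusted p = 0.621 for Fatty acid synthesis and 0.959 for the others. In heart 4 striatal genes were below the filter, and the 9 tested had a median of −0.09. The Striatum difference therefore mostly restates the fall in cerebrum. It does not show an effect of PS that depends on tissue. Among transcripts with several gene symbols or none, 1 of 8604 fell with PS in heart and 0 of 8603 passed in cerebrum in limma. In cerebrum 1249 of these had an unadjusted p under 0.05.

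For the counts of the other comparisons, 3 arrays against 3 allow 10 groupings, too few for a share under 0.05. The real grouping, 1 of the 10, gave 734 in cerebrum, 42 in heart and 9610 between the tissues, and the highest other grouping gave 0 in each.

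Striatal transcripts were lower in the PS cerebra, with all 12 tested genes below every MCT array in each of PS 1, PS 2 and PS 3. Less subcortical tissue in the dissected samples is a candidate explanation that the lists of other regions are consistent with: the Cerebral cortex list had a median of 0.49, while the medians of the Thalamus, Hypothalamus and Myelin lists were −0.40, −1.05 and −0.49. Neither the Thalamus nor the Hypothalamus list passed its own test. The Hypothalamus list had 5 tested genes, and cerebrum MCT 3 lay below PS 3 for it, so it did not separate the treatments. Of the 10 tested Thalamus genes 7 were lower and 3 higher. The array with the male pattern, PS 2, lay at −2.29, but a single array of a sex excludes nothing, so sex cannot be told apart here. PS also stays open, untested: its smallest difference was −0.71, in PS 3, below all MCT arrays, which other causes would give as well.

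Glucocorticoid response genes were higher in the PS arrays of both tissues. Less subcortical tissue stays open as a cause in cerebrum. The list's mean difference was 0.58 ± 0.10 (SE) without and 0.80 ± 0.14 with the Striatum mean as a covariate, with a lower 95% confidence limit of 0.36. The difference thus did not shrink with this covariate. Treatment and the covariate correlated at −0.837, however, so the fit separates them poorly and cannot decide the question. PS and sex cannot be told apart. In heart they coincide, and in cerebrum PS 2 was the only PS array with the male pattern. Its list median of 0.34 was the lowest of the 6 PS arrays (0.337) and above every MCT array of both tissues. In contrast, Fkbp5 in PS 2, at 6.37, lay below every cerebrum MCT array (6.55 to 6.83), and a single array excludes nothing.

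The medians of small nuclear and nucleolar RNAs and of ribosomal protein transcripts were lower with PS in both tissues. Of the small RNA genes, 9 of 36 passed over all transcripts as lower and 1 as higher in cerebrum, and 2 of 38 as lower in heart. Among all gene symbols tested, counting those with any transcript past, 454 of 11234 were lower in cerebrum and 12 of 11151 in heart. Heart MCT 3 stood with the PS arrays for Snora44, a gene chosen after its values were seen. There it was 6.58, against 6.67 to 7.07 in the PS hearts and 9.92 and 9.57 in MCT 1 and MCT 2. Scaling of whole arrays is argued against, since after quantile normalization the small RNAs still lay at −0.37 (cerebrum) and −0.61 (heart) relative to all genes. Differences in RNA preparation between single samples are a candidate explanation: within groups both kinds of transcript varied together over the 12 arrays (Pearson r = 0.914, exact permutation p = 0.0340 over 1296 arrangements, adjusted 0.0340; Spearman rho = 0.895, exact permutation p = 0.0316, adjusted 0.0340), and r was 0.741 without heart MCT 3 and cerebrum MCT 3. The deviations behind the 0.741 were still taken from group means that included those MCT 3 arrays. It therefore does not show that the correlation holds without them. Any cause that moves both kinds together would give such a correlation, so it does not favour RNA preparation over others. No measure of RNA quality was examined. Sex and PS cannot be told apart, with the male-pattern array at −0.42 and the highest PS array at −0.18, and neither was tested further.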

How the results depend on the processing

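The alternatives with a Striatum or sex covariate, with selected arrays left out together, with small RNAs left out and with the filter applied in both tissues were chosen after the data were seen, and unless a value shows it the cause was not tested. Named genes and lists kept their direction in all alternatives except 3 lists under the Striatum covariate: Striatum (median 0.0453), for which that covariate fixes the outcome, Cerebral cortex (−0.17) and Endothelial cells (−0.17). The Clock genes also had a median of −0.05 there, while their test stayed upward. Of the values for named genes, 440 in cerebrum kept their side of the threshold and 300 lost the call, 439 and 124 in heart with 21 gained, and 256 and 8 for the difference between tissues. For lists past the threshold, 151 kept it and 54 lost it in cerebrum, and 77 and 14 in heart.

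For PS against MCT in cerebrum 734 transcripts passed, against 189 over all transcripts of the table, 6 with a plain t statistic, 3407 with array weights, 371 with all 12 arrays in 1 fit, 366 with equal treatment and number across tissues as a random block, 2148 at an adjusted p under 0.10, 12 with PS 3 alone, 0 with MCT 3 alone (829 at an unadjusted p under 0.05) and 0 to 1557 leaving out 1 array. A lone array was assumed to vary like the other group. With the Striatum mean as covariate 1 passed (1327 at an unadjusted p under 0.05): Tac1, part of that mean, went from −3.01 ± 0.67 to −0.21 ± 0.16 (SE), whereas Ecel1 went from −2.51 ± 0.20 to −1.90 ± 0.27 and Cdkn1a from 1.31 ± 0.20 to 1.93 ± 0.27, with wider errors and fewer degrees of freedom. With sex pattern as covariate 799 passed, 304 of them shared with the 734, and this effect rests on PS 2, the only male-pattern PS array. For PS against MCT in heart 42 passed, against 17 over all transcripts, 3 with a plain t statistic (Xist, Eif2s3y and Uty), 6987 with array weights, 1722 with all 12 arrays, 1733 with that random block, 106 at an adjusted p under 0.10, 993 at an unadjusted p under 0.05 and a fold of 1.5, 1176 without MCT 3 and PS 3, 12 without small RNAs and sex-linked genes, and 4 to 3416 leaving out 1 array. For the difference of the PS effect between heart and cerebrum 194 passed, against 294 after median centring, 96 with a plain t statistic, 22 with equal treatment and number as a block (PS 2 differed in sex pattern between tissues), 633 at an adjusted p under 0.10, 1092 at an unadjusted p under 0.05 and a fold of 1.5, 54 with sex as covariate, which here amounts to leaving out cerebrum PS 2, and 3 to 1629 leaving out 1 array. The 9610 of heart against cerebrum in MCT mice stayed within 1.5 times, at 8619 to 10315 leaving out 1 array. Array weights gave convergence warnings in all comparisons but cerebrum, and gave 1 heart array, MCT 2, a weight of 38.9. Lists past the threshold were 13 in cerebrum, against 0 with an estimated correlation (2 at an unadjusted p under 0.05), 4 with fry, 3 with the Striatum covariate, 6 with PS 3 alone, 7 with MCT 3 alone and 12 to 17 leaving out 1 array. In heart they were 7, against 0 with an estimated correlation (2 unadjusted), 2 with fry, 14 without the filter and 6 to 10 leaving out 1 array.

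Replicate numbers did not pair the arrays in cerebrum. After removal of group means, same-numbered arrays correlated at 0.10, −0.15 and −0.26 there, and arrays of unequal number at up to 0.269. In heart same-numbered arrays correlated at −0.00473, 0.0897 and 0.147. The heart values for numbers 2 and 3 lay above every pair of unequal number, which reached 0.045 at most, so a pairing in heart stays open. With the replicate block 0 passed for PS against MCT in cerebrum (3083 at an unadjusted p under 0.05), 88 for PS against MCT in heart and 143 for the difference of the PS effect between heart and cerebrum. Not every array correlated best with its own number.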

Other observations

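Values per array showed differences within groups that the labels do not describe, and the choice of these transcripts followed a look at the values. Ttr, the thyroxine carrier made in bulk by the choroid plexus, was 10.82 and 11.54 in cerebrum MCT 1 and MCT 2 and 5.98, 6.7, 4.34 and 6.6 in MCT 3, PS 1, PS 2 and PS 3. The atrial myosin light chain Myl7 was 8.53 in heart MCT 3 and 6.80 in heart PS 3, against 4.16 to 5.08 in the other 4 heart arrays. The list of fibroblast and extracellular matrix genes had a median of 2.07 relative to the MCT mean in heart PS 2, against 0.12 in PS 1 and 0.155 in PS 3. The Hypothalamus list was at −0.77 in cerebrum MCT 3, close to −0.66 in PS 3.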
